A study of Zea mays with 32 samples.

How the data were processed

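mRNA was sequenced from 32 pooled samples of maize inflorescences: 6 libraries of B73 ear sections, 6 of B73 tassels and 20 of ears from wild type and the mutants ra1-R, ra2-R and ra3-fea1. Per the labels' protocols, the mutant alleles had been introgressed at least 6 times into B73 and the plants of that series were grown in the field, while the B73 developmental series came from a greenhouse. Per the series description, the wild-type samples of the mutant series are proportional mixtures of heterozygous siblings from the 3 mutant populations. Ear sections were pooled from about 30 ears, tassels from 20 to 30, and mutant-series ears from 9 (1 mm class) or 6 (2 mm class). Per the labels' protocols the libraries are paired-end and not strand-specific, so reads of overlapping antisense genes cannot be told apart.

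The values are FPKM (fragments per kilobase of transcript, scaled to the size of the library), computed by the authors in each library on its own. Per the submitters' processing notes, CASAVA, TopHat 1.2.0, Cufflinks and Cuffdiff 1.0.2 were used, with neither their roles nor their order given. The loci carry the prefix of the AGPv2 assembly of B73 per the deposited tables, and the gene models have GRMZM and AC_FG identifiers. The tables of FPKM per gene and library were used. The authors also deposited tables with 1 FPKM value per group, each scaled on its own. These were read only to compare median ratios and fold changes across genes. Transcript-level tables per library were deposited too and were not analysed here. How the authors shared reads between near-identical copies is not stated, so members of close gene families, such as the SBP-box and MADS-box genes, are uncertain to that extent. The tables give a status per gene, which was OK for 39575 to 39613 of the 39636 genes in a library; a value with another status was taken as missing.

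The tables list no counts, so depth was inferred from the width of the FPKM confidence bounds as if set by counting error alone: 3366725 to 23607624 fragments per library. The sum of FPKM per library ran from 269894 to 521544.8, so values as deposited are not on an equal total. Replicates correlated across genes at r of 0.977 to 0.988 in ear sections, 0.861 to 0.901 in tassels, 0.903 to 0.965 in 1 mm ears and 0.897 to 0.967 in 2 mm ears; these are values across genes, which are not independent replicates. The reference gene table held 18774 of the 39636 identifiers and a symbol for 2650. The identifier of ra2 was taken from background knowledge and checked by its neighbours, of which 18 of 18 lie beside it in that table as well. Where the table and the fixed lists give an identifier different symbols (GRMZM2G102161 is zmm14 in the table and zmm8 in the list), the table's symbol is printed. The symbol M14 is shared by GRMZM2G032070 and GRMZM2G099522, and M14 without an identifier means GRMZM2G032070 below. Coordinates are those of the deposited tables. No genome sequence was at hand, so GC content and gene length were not checked.

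Fold changes and tests were computed on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with values as deposited and no further scaling, group means, empirical Bayes with a mean-variance trend, and Benjamini-Hochberg adjustment over the genes tested; a gene was called at an adjusted p under 0.05. Genes with FPKM of at least 1 in at least 2 libraries of a fit were kept. A fit was made for each of the 3 series, over 6, 6 and 20 libraries, and gave 19 comparisons: sections with sections, stages with stages, each mutant with wild type at each size, wild type between sizes, mutants with each other at 2 mm, and the change of each mutant effect between sizes. Tests are two-sided. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

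Gene lists of at least 5 measured members were tested against all other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. These tests and the counts of list members use the members with a value in every library of the series. A list's position is its median log2 fold change minus that of all genes. 20 lists were fixed before the data were examined, as were the comparisons and all alternatives except the replicate block with median shift. Among these lists, photosynthesis genes were fixed as markers of green leaf or husk tissue, and heat shock genes as signs of handling. A further 27 lists were added after the reference table, library totals, the ramosa genes' levels and the correlations between libraries had been seen, and before any comparison was computed. The genes to be named were set by a rule fixed at the same time as the first lists: ra1, ra2 and ra3 in every group; per fixed list the 2 to 4 members with the smallest adjusted p, and every member of a list with fewer than 5; and for ear base against tip, tassel stage 3 against 1, each mutant against wild type at 2 mm and wild type 2 mm against 1 mm, the 10 highest and 10 lowest log2 fold changes among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and groups that do not overlap. Genes without a symbol were counted, and those named were chosen after their values were seen.

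The alternatives were a pseudocount of 0.1, no filter on low values, a shift of every library to a common median of log2(FPKM + 1) (the common median), the replicate number as a block, the block with the shift, a fit over the compared groups only, and each library left out in turn; an estimated correlation for lists, ear position sets limited to changes of at least 1 on the log2 scale, and for ear against tassel a mean of at least 5 FPKM in both series. Whether replicate numbers pair the libraries was checked by the correlation across genes of deviations from the group means. In 2 mm ears, same-numbered libraries of any pair of mutants correlated at 0.143 to 0.686. The numbers were therefore taken to pair the samples in the 3 comparisons between mutants, though the labels name no shared day or batch. These correlations were computed without the common median. Replicate 3 had the lowest sum of FPKM in every 2 mm group, so unequal totals may contribute to them, which was not tested. Library numbers in the names of the deposited tables fall in separate runs, which at 2 mm go with the replicate numbers and at 1 mm do so for wild type and ra1 alone, a hint at separate rounds of preparation or sequencing that no label states.

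The fit was tested on simulated data for the genes of each comparison, with 80 genes changed by 1, 60 by 2 and 60 by 4 on the log2 scale. With spreads moderated by limma, changes of 2 were recovered for 100% of genes in ear base against tip and in base against middle, 18.33% in tassel stage 3 against 1, 83.33% in ra1 against wild type at 2 mm, 61.67% at 1 mm, 85% in ra1 against ra2 and 65% in wild type 2 mm against 1 mm. With the raw residual spread of each gene the same shares were 91.67%, 96.67%, 0%, 70%, 41.67%, 81.67% and 78.33%, so the tassel fit finds few changes at this spread. Tassel changes of 4 were recovered for 83.33% of genes with moderated spreads and 0% with raw ones. False calls among unchanged genes numbered 22, 26, 4, 8, 5, 6 and 9 in the same order with moderated spreads. With raw spreads they numbered 5, 4, 0, 11, 6, 1 and 4. In each of the 2 ear comparisons, 77, 60 and 60 genes changed by 1, 2 and 4 were recovered with moderated spreads. For the mutants' shared changes, 100 draws of unchanged groups were simulated. Residuals were permuted over all 2 mm libraries, wild type included, and the mutants of a draw were compared with a wild-type group in common.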

Results

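Transcript levels were measured by mRNA sequencing in 32 libraries of maize inflorescences, each made from a pool of dissected ears or tassels. 6 libraries came from ears 10 mm long of the inbred line B73, which were divided along their axis into a tip of 1 mm (inflorescence and spikelet pair meristems, per the labels), a middle section of 1 mm (spikelet meristems) and a base section of 2 mm (floral meristems), with 2 libraries per section. Another 6 came from B73 tassels of 1 to 2 mm (stage 1), 3 to 4 mm (stage 2) and 5 to 7 mm (stage 3), with 2 libraries per stage. The remaining 20 came from ears of wild-type plants and of the branching mutants ra1, ra2 and ra3, in a 1 mm class (0.7 to 1.5 mm; 2 libraries of 9 ears per genotype) and a 2 mm class (1.8 to 2.5 mm; 3 libraries of 6 ears per genotype). The tables give FPKM for 39636 gene models and list no read counts. The confidence bounds of the values imply 3366725 to 23607624 fragments per library (median 8156081.5), if counting error alone sets them, and 17238 to 21539 genes reached 1 FPKM. Levels are given below as mean FPKM ± SD over the libraries of a group, with n = 2 in ear sections, tassels and 1 mm ears and n = 3 in 2 mm ears. A log2 fold change is the difference of log2(FPKM + 1).

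The ramosa genes themselves were read in every group first. ra1 (GRMZM2G003927) encodes a zinc-finger transcription factor, ra2 (AC233943.1_FG002) a LOB-domain transcription factor and ra3 (GRMZM2G014729) a trehalose phosphate phosphatase, and all 3 limit the branching of the inflorescence. On the AGPv2 assembly ra1 lies on chromosome 7 at 110331505 to 110332253, ra2 on chromosome 3 at 12882491 to 12883276 and ra3 on chromosome 7 at 166856424 to 166860909. Along the B73 ear, ra3 stood at 67.7 ± 6.78 FPKM in the tip, 8.52 ± 1.97 in the middle and 1.61 ± 0.258 in the base. ra2 was highest in the middle section (29.5 ± 0.455, against 14.8 ± 1.75 in the tip and 19.1 ± 0.185 in the base), and ra1 stood at 12.5 ± 2.99, 10.7 ± 3.01 and 9.14 ± 2.61. Between base and tip, ra2 differed by 0.35 (adjusted p 0.0633) and ra1 by -0.42 (0.169). When each library was shifted to a common median log2 value, a setting called the common median from here on, ra2 turned to -0.07 and ra1 passed (-0.84, adjusted p 0.0185), and without tip replicate 2 ra2 passed (0.0221). In tassels of stages 1, 2 and 3, ra3 stood at 18.8 ± 2.51, 29.3 ± 10.8 and 4.52 ± 3.54, ra2 at 28.2 ± 7.52, 26.5 ± 5.13 and 12.3 ± 3.65, and ra1 at 4.76 ± 1.17, 12.4 ± 4.06 and 5.44 ± 0.980; no change between tassel stages passed the test for these genes.

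In ears of the mutant series, each gene was still detected in its own mutant. At 2 mm, ra1 stood at 18.6 ± 3.24 FPKM in wild type and 26.4 ± 7.06 in ra1 mutants (log2 fold change 0.46, adjusted p 0.463). ra2 stood at 18.0 ± 3.38 in wild type and 8.02 ± 3.30 in ra2 mutants (-1.13, adjusted p 0.725), and ra3 at 47.4 ± 16.3 in wild type and 21.2 ± 8.54 in ra3 mutants (-1.15, adjusted p 1). At 1 mm, the corresponding pairs were 7.87 ± 0.0643 and 11.3 ± 0.413 for ra1, 18.0 ± 3.83 and 12.5 ± 8.16 for ra2, and 37.7 ± 1.27 and 16.5 ± 9.74 for ra3, none past the test (adjusted p 1, 0.977 and 0.695). The labels do not say what each allele does to its transcript, so these levels do not check the genotype labels. Under the common median, ra2 at 2 mm in its mutant passed the test (-1.41, adjusted p 0.0257), and so did ra1 in the ra2 mutant (9.51 ± 2.00 FPKM; -1.18, adjusted p 0.0257), against -0.90 and an adjusted p of 0.725 as deposited.

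**Figure D1:**
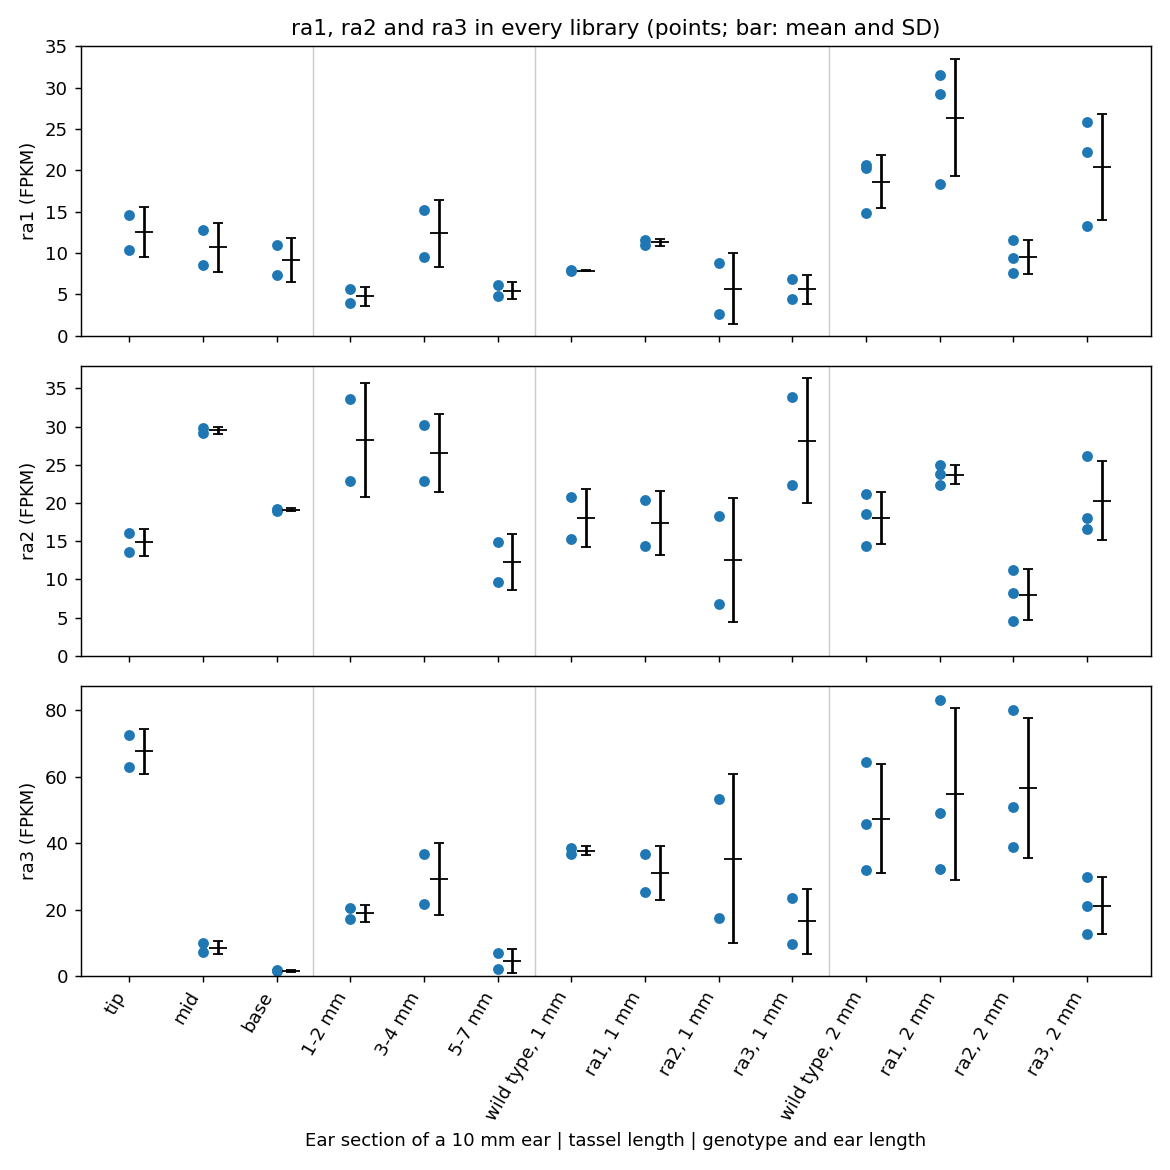
FPKM of ra1, ra2 and ra3 in each library, on a linear axis, with points for single libraries and bars for the group mean and SD. ra3 falls from 67.7 FPKM in the ear tip to 1.61 in the base, and each gene remains detected in its own mutant.

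The comparison of ear base with ear tip asks which transcripts separate floral meristems from the inflorescence and spikelet pair meristems above them. Floral identity genes were higher in the base: of 17 measured floral MADS-box genes 15 rose and 1 fell (adjusted over the list alone, 15 rose and 1 fell). bde1 (GRMZM2G160565), a floral regulator, went from 0.0281 ± 0.0398 to 17.7 ± 2.64 FPKM (4.18, adjusted p 1.11e-06), si1 (GRMZM2G139073; silky1, a stamen and lodicule identity gene) from 0.569 ± 0.733 to 30.1 ± 0.838 (4.39) and zag2 (GRMZM2G160687), of the ovule and carpel class, from 0.0285 to 9.15 ± 0.132 (3.30). The member that fell was zap1 (GRMZM2G148693), at 96.6 ± 0.0129 in the base and 210.8 ± 5.56 in the tip (-1.12, adjusted p 0.000171). All 8 measured YABBY genes, which mark lateral organs, rose, among them yab9 (2.07 to 32.2 FPKM, 3.43) and yab10 (2.03 to 18.7, 2.69); YAB3 reached 7.05 FPKM against libraries listed at 0. Counts adjusted over the list alone were also 8 of 8. Under the common median 12 MADS-box genes rose and 1 fell, and all 8 YABBY genes still rose.

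Genes of the meristems themselves went both ways. ra3 fell by 4.72 on the log2 scale (SE 0.19, adjusted p 9.92e-07). Of 5 measured genes for axillary meristem initiation 3 fell and none rose (the same adjusted over the list alone). BA1 (GRMZM2G397518, barren stalk1) stood at 25.7 ± 2.42 in the base against 76.2 ± 14.9 in the tip (-1.52, adjusted p 0.000167), BIF4 at 3.28 against 8.27 (-1.14) and bif2 (barren inflorescence2) at 4.14 against 7.15 (-0.67, a call that is lost without base replicate 2, adjusted p 0.1). Of 15 cytokinin genes 3 rose and 5 fell, over all genes and adjusted over the list alone, with crr1, a response regulator, at 1.21 ± 0.438 against 10.9 ± 1.87 (-2.43) and RR7 rising from 2.75 to 7.75 (1.22); under the common median 2 rose and 8 fell, and all 5 axillary meristem genes fell. kn1 (GRMZM2G017087), a homeobox gene of meristem cells, stood at 141.2 ± 0.717 against 312.8 ± 19.5 (-1.14), while gnarley1 of the same family rose (8.45 to 33.0, 1.85); 6 of 10 KNOX genes rose and 1 fell (6 and 1 adjusted over the list alone; 5 and 4 under the common median). Among 14 genes for spikelet and branch determinacy 5 rose and 4 fell, over all genes and adjusted over the list alone (4 and 7 under the common median). bd1 (GRMZM2G307119, branched silkless1), a determinacy factor of the spikelet meristem, went from 0.486 ± 0.0208 to 7.30 ± 0.379 (2.48, adjusted p 9.94e-06), and GRMZM2G180190, the LEAFY homologue zfl2 by its identifier, fell from 65.4 to 16.8 (-1.89).

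The lists for SBP-box, auxin and meristem size genes were not called as groups, though single members passed. Of 23 SBP-box genes 15 rose and 3 fell (16 and 3 adjusted over the list alone; 11 and 5 under the common median), with tga1, the glume architecture gene, at 1.17 in the tip and 17.8 in the base (3.12). Of 19 auxin response and transport genes 14 rose and 1 fell, over the list alone too (9 and 2 under the common median), led by ARF9 (5.82 to 35.8, 2.44). Of 7 genes for meristem size 4 rose and 2 fell, with fea3, a receptor gene, at 2.30 against 18.0 (2.52) and FEA4, a bZIP gene, at 30.6 against 9.94 (-1.53). 6 of 7 photosynthesis genes, fixed as markers of green leaf or husk tissue, rose and none fell, at low levels (cp29 3.81 ± 0.217 in the base, 0.0285 in the tip). The PEBP gene ZCN4 rose from 0.782 ± 0.146 to 8.74 ± 0.453 (2.45). The named genes with the widest differences toward the base were M14 (GRMZM2G032070; 0.634 ± 0.331 to 63.7 ± 1.87 FPKM, 5.32), thi1-2 (4.85), pcr1 (4.42), si1, bde1, yab14 (4.07), MADS4 (3.99), G1 (3.88), zmm27 (3.82) and MYB59 (3.49). Toward the tip they were MPI (GRMZM2G028393), a proteinase inhibitor gene (143.7 ± 3.38 in the tip, 0.440 ± 0.438 in the base, -6.68), ra3, PIP2-6 (-4.24), lox1 (-2.71), Lsi1 (-2.64), cyp78 (-2.57), ALDH12 (-2.54), SGR2 (-2.50), chiA (-2.45) and crr1. All of these 20 genes kept their direction and their call under the common median.

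limma called 12413 of 21110 genes between base and tip, 10448 higher in the base and 1965 lower, with 8233 called when base replicate 1 was left out. The median log2 fold change of all genes was 0.47. With the libraries shifted to a common median, 10226 genes were called, 5455 higher and 4771 lower, of which 7420 were shared with the calls without the shift, so the excess of higher genes is not independent of scaling. Relative to all genes, the lists moved by 1.55 (floral MADS-box, camera adjusted p 0.00062), 2.38 (YABBY, 0.000103), -1.14 (axillary meristem initiation, 0.00062), -0.56 (cytokinin, 0.00354) and 0.83 (photosynthesis, 0.0287). None of these holds with an estimated correlation (adjusted p 0.662 for the first 4, 0.933 for photosynthesis), nor does any other list call below, where the smallest such value is 0.201. The lists for determinacy, KNOX, SBP-box, auxin and meristem size were not called (adjusted p 0.0881, 1, 0.420, 0.138 and 0.749).

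**Figure D2:**
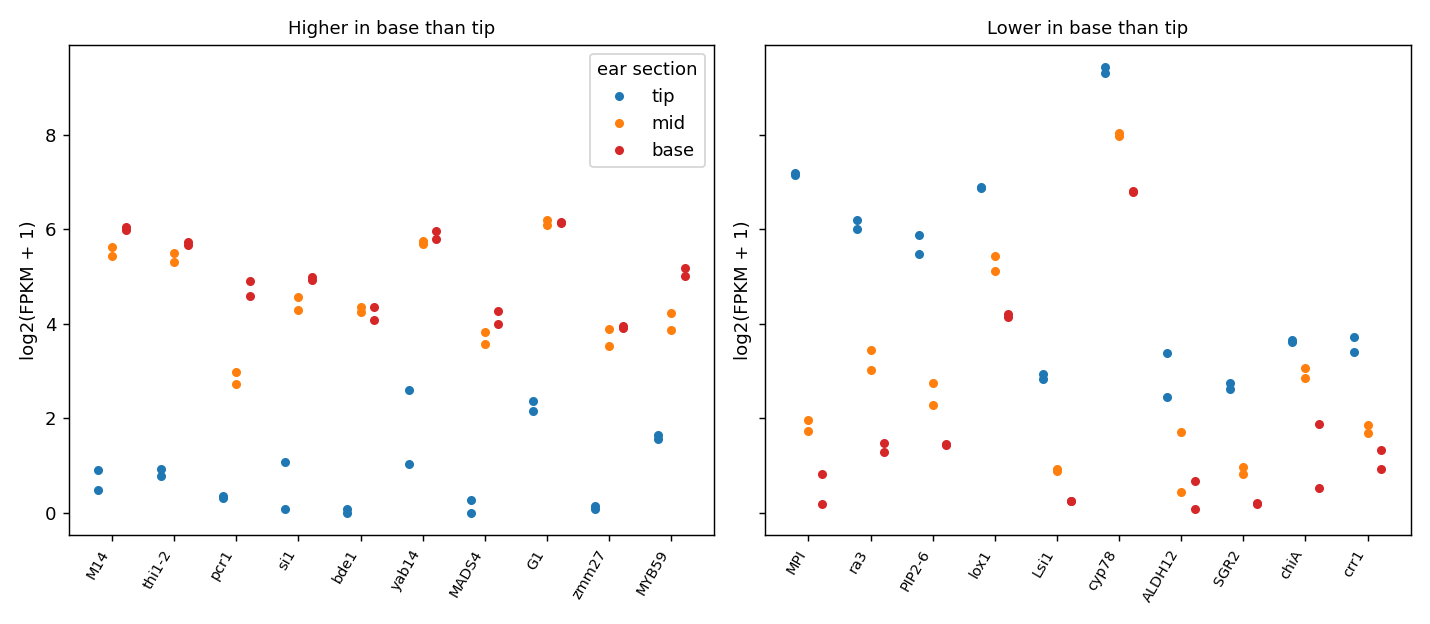
log2(FPKM + 1) in each ear tip, middle and base library, for the 20 named genes with the widest differences between base and tip. The log2 fold change of base over tip is highest for M14 at 5.32 and lowest for MPI at -6.68, and is -4.72 for ra3.

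The middle section against the tip asks what changes when spikelet meristems follow spikelet pair meristems. The rise of floral and organ genes was already present there: bd1 stood at 11.2 ± 1.19 FPKM against 0.486 in the tip (3.03, adjusted p 6.36e-06), bde1 at 18.8 against 0.0281 (4.27), yab9 rose by 3.64, gnarley1 by 1.92, fea3 by 1.83 and tga1 by 2.62 on the log2 scale. Of 8 YABBY genes 7 rose and none fell (7 adjusted over the list alone), of 17 floral MADS-box genes 12 rose and 1 fell (13 and 1 over the list alone), and of 14 determinacy genes 8 rose and 4 fell. ra3 fell by 2.86 (adjusted p 1.38e-05) and ra2 rose (0.95, adjusted p 0.000536). BA1 fell (47.2 ± 7.82 against 76.2, -0.68, adjusted p 0.00927), a call lost without middle replicate 2 (adjusted p 0.092). Of 15 cytokinin genes 2 rose and 5 fell (2 and 4 adjusted over the list alone). limma called 13255 of 21113 genes (11314 higher, 1941 lower) at a median of 0.53, and 10558 under the common median (5584 higher, 4974 lower, 7525 shared). The YABBY and cytokinin lists moved by 2.05 and -0.65 relative to all genes (camera adjusted p 0.0109 each; 0.891 with an estimated correlation), and the floral MADS-box list was not called (adjusted p 0.0640).

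The base against the middle section asks what separates floral from spikelet meristems. zag2 rose from 0.533 ± 0.0293 to 9.15 ± 0.132 FPKM (2.73, adjusted p 0.000466; 0.0409 and 0.038 without middle replicate 1 or 2), and YAB6 from 0.314 to 5.31 (2.28, adjusted p 0.00348; 0.0761 without middle replicate 1). Without base replicate 1 or 2, zag2, YAB6, zmm29, Cab-m7 and psa6 fell below the filter and were not tested. No gene was called without base replicate 2. ZAG1 (3.99 to 11.3, 1.30) and zmm29 (1.13) rose too, so that 3 of 17 floral MADS-box genes rose and none fell (5 and none adjusted over the list alone). Of 7 photosynthesis genes 4 rose (6 over the list alone), with Cab-m7 at 1.51, psa6 at 1.55 and cp29 at 1.37 on the log2 scale. Lower in the base were ra3 (-1.86, adjusted p 0.00409), GRMZM2G180190 (-1.35, adjusted p 0.00886) and zfl1 (-0.96), which are the 3 of 14 determinacy genes that fell (2 rose and 8 fell over the list alone), and BIF4 (-1.32) and bif2 (-1.0) of the 5 axillary meristem genes (all 5 fell over the list alone). The calls of ZAG1, zmm29, Cab-m7, psa6, cp29, GRMZM2G180190, zfl1, BIF4 and bif2 were each lost without middle replicate 1 or without middle replicate 2 (adjusted p 0.0761 to 0.395). Of the 6 still tested, all were lost without base replicate 2 (0.0901 to 0.533), and all but BIF4 (0.0487) without base replicate 1 (0.0639 to 0.147). The ra3 call was lost without middle replicate 1 (adjusted p 0.0856), middle replicate 2 (0.0804) or base replicate 2 (0.0521).

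limma called 178 of 21125 genes in that comparison, 93 higher and 85 lower in the base. The count rests on single libraries: without middle replicate 1 it was 2, without middle replicate 2 it was 3, without base replicate 1 it was 28 and without base replicate 2 it was 0, and with no filter on low values 2, while a fit over the compared groups only gave 611 (2186 genes had an unadjusted p under 0.05 with all libraries). Relative to all genes the lists moved by 0.28 (floral MADS-box, camera adjusted p 2.09e-07), 0.33 (YABBY, 0.000414), 0.99 (photosynthesis, 9.93e-11), -0.44 (determinacy, 3.78e-05) and -0.79 (axillary meristem initiation, 6.34e-07), and with an estimated correlation the adjusted p values were 0.400 to 0.615.

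The tassel series asks what changes as the tassel grows from 1 to 2 mm to 5 to 7 mm. Genes of the oxylipin and jasmonate pathway were higher at stage 3: lox10 (GRMZM2G015419) stood at 496.4 ± 13.8 FPKM against 19.2 ± 24.2 at stage 1 (5.52, adjusted p 0.0251), lox6 at 60.8 ± 6.30 against 3.85 ± 3.85 (3.94, 0.0459) and aos1, an allene oxide synthase gene, at 110.5 ± 51.1 against 10.1 ± 5.53 (3.34, 0.0451), the 3 of 20 measured members that rose (8 adjusted over the list alone). SBP-box genes were lower: ub3 (GRMZM2G460544, unbranched3) at 12.1 ± 8.75 against 247.6 ± 121.1 (-4.34, adjusted p 0.0251), sbp6, whose identifier GRMZM2G307588 is that of tasselsheath4, at 8.20 ± 3.32 against 161.4 ± 77.9 (-4.10, 0.0251) and ub2 at 8.52 ± 5.29 against 100.3 ± 38.4 (-3.48, 0.0459). They are the 3 of 24 that fell (6 adjusted over the list alone) and also the 3 of 14 determinacy genes that fell (2 rose and 5 fell over the list alone). zmm14 (GRMZM2G102161) rose from 4.22 ± 1.02 to 62.8 ± 11.9 (3.61, 0.0251) and bde1 from 0.0588 to 10.3 ± 4.97 (3.34, 0.0261), the 2 of 15 floral MADS-box genes past the test (8 rose and 1 fell over the list alone). No YABBY gene passed over all genes, and 6 of the 7 with a value in every tassel library rose adjusted over the list alone.

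Of the other named genes past the test, kin1 (78.1 ± 42.4 FPKM against 0.627, 5.5), RIP, a ribosome-inactivating protein gene (58.2 ± 8.81 against 0.440 ± 0.352, 5.38), and M14 (31.4 ± 4.8 against 0.0391, 4.96) rose most, followed by bx2 (3.93), GST25 (3.86), MPAO (3.48) and EXPA5 (3.44). MADS4 (GRMZM2G097059), a MADS-box gene outside the fixed list, rose from 0.0147 to 7.77 ± 1.36 (3.1, adjusted p 0.0251). GRMZM2G099522, the floral MADS-box list member that shares the symbol M14, was not called (3.92, adjusted p 0.135). Between stages 3 and 2, M14 was the 1 gene called (0.307 ± 0.434 at stage 2; 4.67, adjusted p 0.0264); it was outside the naming rule for that comparison and chosen after its values were seen, and its call is lost without stage 2 replicate 1 (adjusted p 0.144), with a pseudocount of 0.1 (0.327) and under the common median (0.327). Without either stage 3 library, M14, bde1 and MADS4 fell below the filter and were not tested.

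limma called 38 of 21183 genes between stages 3 and 1 (29 higher, 9 lower), 1 of 21183 between stages 3 and 2 (383 at an unadjusted p under 0.05) and 0 of 21180 between stages 2 and 1 (97 at an unadjusted p under 0.05). The median of all genes moved by 0.14, 0.17 and -0.05. With no filter on low values none of the 38 passed (smallest adjusted p among the genes named here 0.319), nor did M14 between stages 3 and 2 (0.765). A fit over the compared groups only called 80 genes between stages 3 and 1. Under the common median 9 genes were called between stages 3 and 1, all among the 38. Of the genes named here kin1, RIP, M14, MPAO and EXPA5 passed, and the others did not (adjusted p 0.064 for ub3, sbp6 and zmm14, 0.271 for lox10). Without stage 1 replicate 1 the 38 became 16 and the calls of lox6, aos1, ub2, bde1, MADS4, zmm14, bx2, GST25, MPAO and EXPA5 were lost (adjusted p 0.0544 to 0.283); the count was 86 without stage 1 replicate 2, 20 without stage 3 replicate 1 (where lox6, aos1, zmm14, MPAO and EXPA5 were lost, adjusted p 0.061 to 0.269) and 94 without stage 3 replicate 2 (where ub2 was lost, 0.12). Between stages 3 and 2 it was 2 and 28 without stage 2 replicate 1 or 2, and 0 and 7 without stage 3 replicate 1 or 2. Between stages 2 and 1 it was 1 and 2 without stage 1 replicate 1 or 2, and 1 and 18 without stage 2 replicate 1 or 2. Relative to all genes, camera placed the jasmonate list at 0.82 (adjusted p 1.13e-10), YABBY at 1.47 (9.52e-10), floral MADS-box at 1.28 (5.67e-05), SBP-box at -0.27 (5.30e-06), determinacy at -1.28 (5.73e-06) and axillary meristem initiation at -1.15 (0.000661) between stages 3 and 1, and with an estimated correlation their adjusted p values were 0.789 to 0.880.

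**Figure D3:**
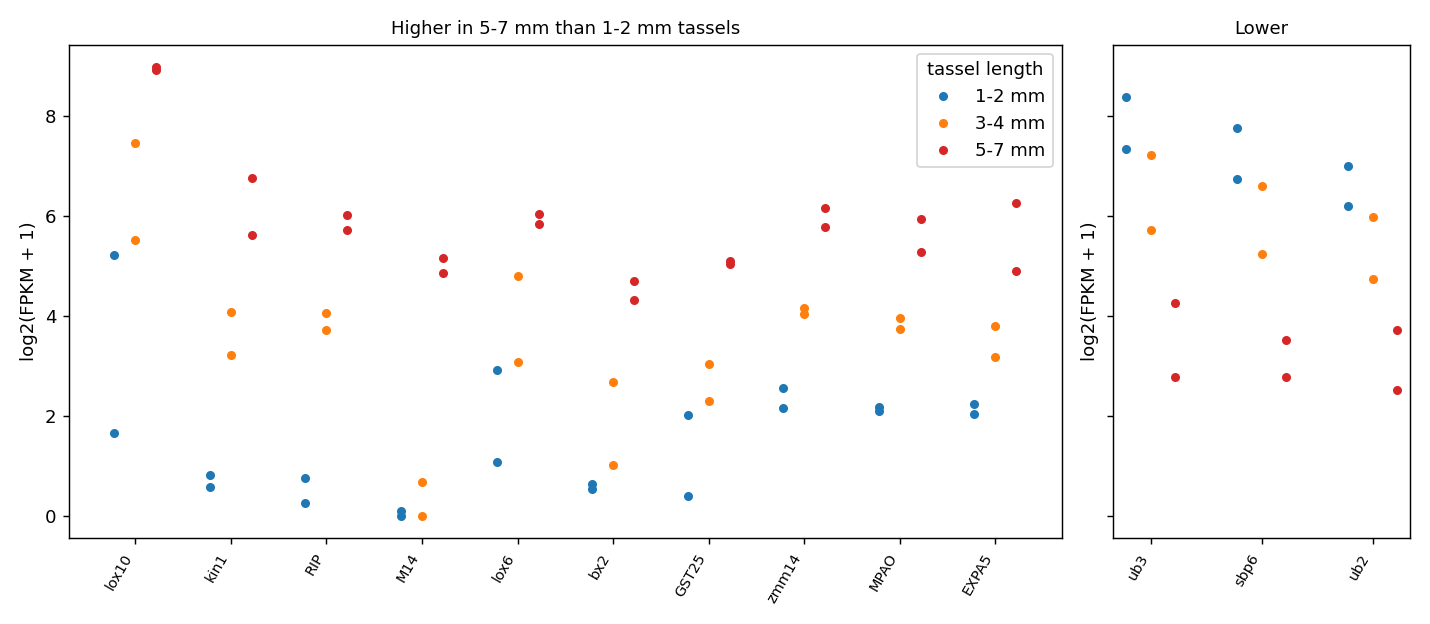
log2(FPKM + 1) in each tassel library, by stage, of the 10 higher and 3 lower genes that the naming rule took between stages 3 and 1. lox10, kin1, RIP and M14 rise with stage, and ub3, sbp6 and ub2 fall.

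Ear position and tassel stage were compared to ask whether the same genes change from younger to older meristems in ears and tassels. Across 19927 genes, which are not independent replicates, the log2 fold changes of ear base over tip and of tassel stage 3 over stage 1 had a Pearson r of 0.164 and a Spearman rho of 0.112. M14, bde1 and MADS4 were called higher in both. Among the genes called in both, 13 were higher in both (10.5 by chance from the sizes of the lists), 4 were lower in both (0.650), 2 were higher in the ear base and lower in the late tassel (3.48), and 7 were lower in the ear base and higher in the late tassel (1.95). With a pseudocount of 0.1 these were 9 (8.89 by chance), 7 (0.902), 1 (4.94) and 7 (1.62). Among genes with a mean of at least 5 FPKM in both they were 7 (4.89), 2 (0.441), 1 (1.96) and 3 (1.1). The r was 0.315 without stage 1 replicate 1, 0.0350 without stage 1 replicate 2 and 0.0504 without stage 3 replicate 1.

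Ears of 2 mm against 1 mm were compared in the wild type, a mixture of heterozygous siblings of the mutants, to ask what changes with growth. bd1 rose from 0.0271 ± 0.0227 to 1.74 ± 0.598 FPKM (1.39, adjusted p 0.0377), in all 3 of the 2 mm libraries. GRMZM2G050412 rose from 55.1 ± 15.4 to 240.7 ± 51.3 (2.11, adjusted p 0.00995) and GRMZM2G430807 from 26.4 ± 7.99 to 103.7 ± 22.5 (1.94, adjusted p 0.0348); the tables pair neither with a symbol, and both were chosen after their values were seen. ra1 went from 7.87 ± 0.0643 to 18.6 ± 3.24 FPKM, which did not pass (1.13, adjusted p 1; 0.0676 under the common median). Of 15 jasmonate genes and 18 auxin genes none passed, but the lists stood 0.28 and 0.24 above all genes (camera adjusted p 0.00599 and 0.0363), and 14 heat shock genes stood at -0.33 (0.0064), none holding with an estimated correlation (0.991 each). limma called 12 of 21652 genes, all higher at 2 mm; 2 were called without 1 mm wild-type replicate 1 and 0 without 1 mm replicate 2, 2 mm replicate 1 or 2 mm replicate 2. bd1 was then at an adjusted p of 0.366, 0.342, 0.0932 and 0.221, and at 0.119 under the common median. GRMZM2G050412 was lost without 1 mm replicate 2 (0.258), 2 mm replicate 1 (0.0932) or 2 mm replicate 2 (0.0705), and GRMZM2G430807 without any of these 4 libraries (0.0932 to 0.528).

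The mutant comparisons ask which transcripts depend on each ramosa gene in young ears. In 2 mm ra1 mutants the determinacy gene bd1 was nearly silent, at 0.00625 ± 0.0108 FPKM against 1.74 ± 0.598 in wild type (-1.42, adjusted p 0.00575), lower in 3 of 3 libraries and the 1 of 14 determinacy genes to pass (1 adjusted over the list alone). It lies on chromosome 7, at 172207717 to 172209213, as ra1 does. cc3 (GRMZM2G440968), on chromosome 6, fell from 13.5 ± 2.74 to 3.58 ± 1.21 (-1.67, adjusted p 0.00843) and is the only symbol that the naming rule took. Among genes without a symbol, GRMZM2G430807 fell from 103.7 ± 22.5 to 9.96 ± 0.466 (-3.24, adjusted p 3.68e-05), GRMZM2G134496 rose from 1.60 to 12 (2.34, adjusted p 0.000325) and GRMZM2G061499 from 0.718 to 9.57 (2.61, adjusted p 0.000475), all 3 chosen after their values were seen. Of the other fixed lists no member passed, and none was called. limma called 32 of 21657 genes (14 higher, 18 lower), 14 of them on chromosome 7, at a median of 0.34. Under the common median 60 were called (11 higher, 49 lower, 24 shared), bd1 and cc3 among them. In a fit over the compared groups only, 2 genes were called, GRMZM2G430807 (0.00206) and GRMZM2G061499 (0.0293), and not bd1 (0.221) or cc3 (0.239). With a pseudocount of 0.1 the count was 17. It was 21, 5 and 19 without wild-type replicates 1, 2 and 3, and 14, 20 and 16 without ra1 replicates 1, 2 and 3. bd1 was lost without wild-type replicate 2 (adjusted p 0.0646), and cc3 without that library (0.101) or ra1 replicate 2 (0.0597).

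In 2 mm ra2 mutants no gene with a symbol passed the test. Lower were GRMZM2G006884 (0.0338 against 7.42 ± 4.12 FPKM, -2.92, adjusted p 0.00629), GRMZM2G001934 (2.74 against 19.9, -2.47, adjusted p 0.00767), GRMZM2G056022 (0.0288 against 2.00 ± 0.707, -1.52, adjusted p 0.00946) and GRMZM5G855014 (listed at 0 against 2.71 ± 0.796), and GRMZM2G329131 was higher (1.78 against 0.183, 1.23). These are all 5 genes called of 21657, and they were chosen after their values were seen. 5 photosynthesis genes stood 0.27 above all genes (camera adjusted p 0.0383; 0.940 with an estimated correlation), with none past the test over all genes and 2 adjusted over the list alone. At a median of 0.24, 663 genes had an unadjusted p under 0.05. Under the common median 18 genes were called, all lower and 4 of them shared, and GRMZM2G329131 was not (adjusted p 0.53). In a fit over the compared groups only none was called (the 5 genes at 0.0638 to 0.507). Without wild-type replicate 1 the count was 3, GRMZM2G056022 was lost (0.0916) and GRMZM2G329131 too (0.0596). GRMZM2G056022 was also lost without ra2 replicate 1, 2 or 3 (0.102, 0.0591 and 0.0767), and GRMZM2G001934 without wild-type replicate 2 (0.0839) or ra2 replicate 2 (0.0591).

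In 2 mm ra3 mutants 7 genes were lower and none higher, none of them with a symbol. GRMZM2G006884 was listed at 0 against 7.42 ± 4.12 FPKM in wild type (adjusted p 0.00679) and GRMZM5G858730 at 0 against 6.33 (0.0275). GRMZM2G353444 stood at 1.39 against 10.9 (-2.29) and GRMZM2G056022 at 0.0140 against 2.00 (-1.54); these genes too were chosen after their values were seen. 14 heat shock genes, a list fixed as signs of handling, stood 0.44 above all genes, with no member past the test (camera adjusted p 0.00153, and 0.995 with an estimated correlation). Its leading members varied widely between the ra3 libraries: HSP90-1 stood at 82.1 ± 56.6 FPKM, HSP18 at 17.5 ± 16.3, hsp18c at 12.3 ± 12.3 and hsp101 at 7.195 ± 7.81. limma called the 7 among 21655 genes, with 554 at an unadjusted p under 0.05, and 12 under the common median, all lower and 5 of them shared. In a fit over the compared groups only 1 was called, and none of the 7 (adjusted p 0.052 to 0.659). The count was 0, 4 and 1 without wild-type replicates 1, 2 and 3, and 0 without ra3 replicate 1 or 3. Without those last 2 libraries, or without wild-type replicate 1, each of the 4 named genes was lost (adjusted p 0.0516 to 0.136). GRMZM5G858730, GRMZM2G353444 and GRMZM2G056022 were also lost without wild-type replicate 3 (0.147, 0.0627 and 0.0595), and GRMZM5G858730 without ra3 replicate 2 (0.104).

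**Figure D4:**
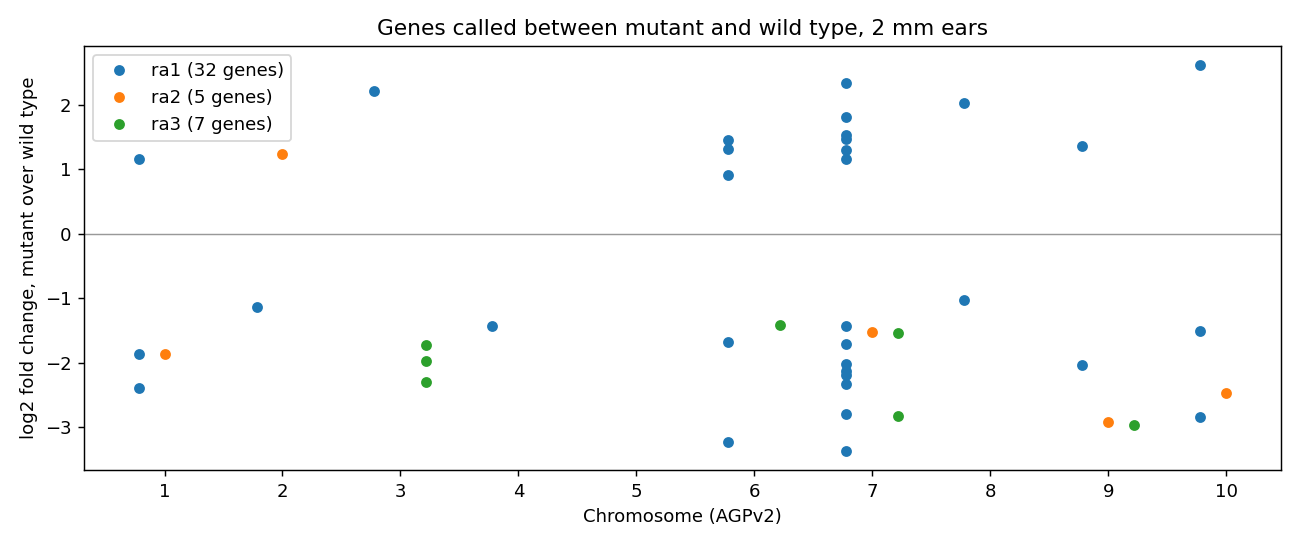
log2 fold changes of the genes called between mutant and wild-type 2 mm ears, by chromosome, for ra1, ra2 and ra3. 14 of the 32 ra1 calls lie on chromosome 7.

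At 1 mm the number of genes that differed between mutants and wild type depended on the fit. limma called 0 of 21651 genes for ra1, 0 of 21646 for ra2 and 1 of 21648 for ra3, with 770, 630 and 1294 at an unadjusted p under 0.05 and medians of 0.08, 0.20 and 0.33. The gene was GRMZM5G847407, at 1.58 ± 0.164 FPKM in ra3 against libraries listed at 0 (adjusted p 0.0276), chosen after its values were seen. It was lost without wild-type replicate 1 (0.0999) or 2 (0.296) and under the common median (0.584). In a fit over the compared groups only, 1, 7 and 161 genes were called for ra1, ra2 and ra3, and with no filter on low values 13, 15 and 22. No BA1, kn1 or determinacy gene passed in the fit over all groups. Heat shock genes in ra2 stood at -0.45 relative to all genes (camera adjusted p 0.00942; 0.993 with an estimated correlation). For ra3 the count was 0 without wild-type replicate 2, 20 without ra3 replicate 1 and 3 without ra3 replicate 2, and for ra2 it was 1 without ra2 replicate 2. The change of each mutant effect from 1 mm to 2 mm was tested as well: limma called 0 genes for ra1, ra2 and ra3, with 430, 194 and 570 at an unadjusted p under 0.05. That count became 1 for ra2 without 1 mm ra2 replicate 2, and for ra3 2 without 1 mm ra3 replicate 1 and 1 without 2 mm wild-type replicate 3.

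The mutants at 2 mm were also compared with each other, which asks where the 3 genotypes part. bd1 was lower in ra1 than in ra2 (0.00625 against 1.07 ± 0.162 FPKM, -1.04, adjusted p 0.0391; 0.0683 under the common median) and than in ra3 (2.39 ± 1.05, -1.71, adjusted p 0.000378). lox1 (GRMZM2G156861) was lower in ra1 than in ra3 (8.92 ± 2.81 against 34.7 ± 9.66, -1.86, adjusted p 0.00428), as was DL1 (GRMZM2G088309), a YABBY gene (1.13 against 5.52, -1.65, adjusted p 0.0197). tga1 was higher in ra2 than in ra3 (2.96 ± 0.765 against 0.808 ± 0.235, 1.12, adjusted p 0.0362; 0.177 under the common median). Of 5 photosynthesis genes 2 rose in ra2 against ra3 (2 adjusted over the list alone), CP24 (2.58 ± 1.49 against 0.244, 1.45) and cp29 (2.39 against 0.144, 1.48), which were not called under the common median (adjusted p 0.0642 and 0.0722). In ra1 against ra2 none of the 5 passed and 3 fell adjusted over the list alone. With the replicate number as a block CP24 and cp29 passed (0.0448 each, against 0.0597 and 0.0676). CP24 did so under the common median too (0.0482). Outside the fixed lists, and chosen after their values were seen, TIM was lower in ra2 (18.9 ± 7.17) than in ra1 (84.7 ± 20.5; 2.16, adjusted p 0.0022) and ra3 (63.3 ± 13.5; -1.75, adjusted p 0.0181), BAD1 was higher in ra1 than in ra2 (13.9 ± 2.84 against 2.77 ± 0.865, 2.00, adjusted p 0.0022), and glb1, a globulin gene, was lower in ra2 than in ra3 (2.29 ± 0.429 against 20.7 ± 6.98, -2.67, adjusted p 0.0011).

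The genes ra2 and ra1 themselves were higher in ra1 than in ra2 mutants by 1.52 and 1.36, not past the test (adjusted p 0.0725 and 0.158). With the replicate number as a block they passed (0.0164 and 0.0316), as they did under the common median (0.00409 and 0.00287). In ra2 against ra3 mutants the genes ra2 and ra1 stood at -1.28 and -0.99, not past the test (limma adjusted p 0.207 and 0.536). Under the common median they passed there too (-1.55 and -1.26, adjusted p 0.0043 and 0.00564). limma called 72 of 21659 genes for ra1 against ra2 (38 higher, 34 lower), 108 of 21655 for ra1 against ra3 (65 and 43) and 69 of 21657 for ra2 against ra3 (50 and 19). The median of all genes was 0.10, 0.33 and 0.24. With the replicate number as a block the counts were 96 (48 higher, 48 lower), 154 (101 and 53) and 96 (73 and 23). Under the common median 96, 149 (51 higher, 98 lower) and 83 (39 and 44) genes were called. A fit over the compared groups only gave 31, 25 and 22. Relative to all genes, photosynthesis genes stood at -0.97 in ra1 against ra2 (camera adjusted p 1.84e-05; 0.201 with an estimated correlation) and at 0.30 in ra2 against ra3 (0.00314; 0.565). Heat shock genes stood at -0.89 in ra1 against ra3 (1.66e-07; 0.961) and at -0.69 in ra2 against ra3 (7.70e-07; 0.565), cytokinin genes at 0.22 in ra1 against ra2 (0.0103; 0.968). In ra1 against ra2 the floral MADS-box (-0.35) and meristem size lists (0.19) were called at 0.0473 each and not with the block (0.0636 each), while the cyclins list in ra2 against ra3 was called with the block alone (0.0382 against 0.0583), as was the glutathione S-transferase list in ra1 against ra3 (0.0487 against 0.1). Without a library the counts moved most for ra1 against ra2 to 42 and 44 (ra1 replicates 1 and 3), 41 and 46 (ra2 replicates 1 and 3), for ra1 against ra3 to 70 and 69 (ra1 replicates 1 and 2) and 68 (ra3 replicate 3), and for ra2 against ra3 to 23, 44 and 36 (ra2 replicates 1, 2 and 3) and 44, 38 and 38 (ra3 replicates 1, 2 and 3).

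Whether the 3 mutants share their changes was read from the calls against wild type at 2 mm. GRMZM5G855014 was lower in ra1 and ra2 (listed at 0 in both), and GRMZM2G056022 and GRMZM2G006884 were lower in ra2 and ra3, so that 3 genes were called in the same direction in at least 2 mutants. All 3 were under 0.1 FPKM in all 12 B73 libraries, a level that 25 of the 21657 genes tested share. So were 3 of the 5 genes called in ra2 (Fisher's exact p 1.36e-08), 2 of the 7 in ra3 (2.68e-05) and 6 of the 32 in ra1. Wild type is a mixture of siblings of the 3 mutant populations. An allele silent in B73 and carried by a single population may therefore read as lower in the other mutants. That cannot be told apart here from a shared effect of the mutations. Independent lists would share 0.00332 (ra1 and ra2), 0.00582 (ra1 and ra3) and 0.00129 (ra2 and ra3) genes among the lower calls. Unchanged groups simulated with a wild-type group in common shared 0, 0 and 0.05 on average (highest 0, 0 and 4, over 100 draws). The draws hold no mutant effects, so they cannot say what lists of called genes would share through common controls. Across genes, which are not independent replicates, the log2 fold changes had r of 0.678, 0.404 and 0.298, against means of 0.445, 0.490 and 0.443 over the draws. Each r lay within the range of the draws (-0.426 to 0.9427, -0.4415 to 0.9178 and -0.6753 to 0.8671). Covariances were 0.102, 0.0479 and 0.0307, against means of 0.0425, 0.0479 and 0.0436. They lay within the draws too (-0.0445 to 0.218, -0.0481 to 0.21 and -0.0368 to 0.205). For r and covariance, no excess over shared controls is thus shown. The 3 wild-type libraries cannot be split into parts of at least 2 libraries, so part of the overlap may come from the shared controls.

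Genes that mark position along the ear were then read in the mutants, to ask whether mutant ears resemble younger or older parts of a wild-type ear. The 9799 genes higher in ear base than tip stood above all genes by 0.07 in 2 mm ra1 ears (camera p adjusted over 12 tests 0.0438) and 0.07 in ra2 (0.0119), and the 1882 genes lower in the base stood at -0.13 and -0.12 (0.0119 each). In 2 mm ra3 ears the signs were opposite, at -0.02 (0.0361) and 0.06 (0.0154). At 1 mm the base set stood at -0.01 in ra1 (not called), 0.06 in ra2 and 0.07 in ra3, and the tip set at 0.00, -0.14 and -0.12, the ra2 and ra3 values being called. With sets limited to changes of at least 1 on the log2 scale, the base set was called neither in 2 mm ra1 (unadjusted p 0.884) nor in 2 mm ra2 (0.0699), and the calls of the base set in 1 mm ra2 and of each set in 1 mm ra3 were lost as well. None of the 10 calls among the 12 tests holds with an estimated correlation (adjusted p 0.923 each). The sets come from the ear fit without the common median, and these tests were not run under it. The base set stood higher and the tip set lower where the median of all genes was 0.20 to 0.34. At medians of 0.01 (2 mm ra3) and 0.08 (1 mm ra1) they did not, so ear age and scaling cannot be told apart.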

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

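The tests of linkage to ra1, of genes silent in B73, of the 1 mm to 2 mm ratio, of the 10 highest genes and of a batch shared by a number were chosen only after the result was seen.

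Genes that changed in opposite directions along the ear and over tassel growth stood out, because every library of each group moved its own way; the difference between ear and tassel was not tested. ub2 was higher in ear base than tip (log2 fold change 1.48) and lower in the late tassel (-3.48). RIP moved by -1.99 in the ear and 5.38 in the tassel, bx2 by -1.88 and 3.93, and MPAO by -0.91 and 3.48. Genes without a symbol were GRMZM2G456217 (-2.80 and 4.35), GRMZM2G127379 (-3.87 and 3.43), GRMZM2G470882 (-1.40 and 3.88), GRMZM2G104204 (-1.90 and 3.54) and AC215201.3_FG008 (0.85 and -3.31). Of the tassel calls, those of RIP and GRMZM2G456217 passed without each library in turn. With no filter on low values none of the 9 passed. RIP and MPAO passed under the common median. The others did not: GRMZM2G456217 (0.206), bx2 (0.159), ub2 (0.0671), GRMZM2G127379 (0.0672), GRMZM2G470882 (0.064), GRMZM2G104204 (0.0511) and AC215201.3_FG008 (0.0784). Without stage 1 replicate 1 the other 7 were lost: ub2 (adjusted p 0.16), bx2 (0.0544), MPAO (0.0575), GRMZM2G127379 (0.366), GRMZM2G470882 (0.0936), GRMZM2G104204 (0.0936) and AC215201.3_FG008 (0.104). Without stage 3 replicate 1, MPAO (0.0979), GRMZM2G127379 (0.152), GRMZM2G470882 (0.0663), GRMZM2G104204 (0.0846) and AC215201.3_FG008 (0.115) were lost, as were AC215201.3_FG008 without stage 1 replicate 2 (0.093) and ub2 without stage 3 replicate 2 (0.12).

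A pair of genes changed in opposite directions from wild type between mutants, each by a test of the difference itself. Wild type is a mixture of siblings of the 3 populations, and GRMZM2G056022 was under 0.1 FPKM in all 12 B73 libraries. Among genes called between mutants, wild type lay between the mutants at 62 of 72 (ra1 and ra2), 93 of 107 (ra1 and ra3) and 65 of 69 (ra2 and ra3). These genes were selected for a difference between the mutants, which by itself favours a wild-type level between them. No expected share was computed, so the counts do not bear on the cause. Opposite effects of the mutations cannot be told apart from alleles that differ between the populations. GRMZM2G056022 was higher in 2 mm ra1 ears than in wild type (1.52) and lower in ra2 (-1.52; limma adjusted p of the difference 7.23e-07) and in ra3 (-1.54; 6.49e-07), at 7.53 ± 1.19 FPKM in ra1, 2.00 in wild type, 0.0288 in ra2 and 0.0140 in ra3. GRMZM2G070500 was higher in ra1 (1.31) and lower in ra3 (-1.41; adjusted p of the difference 4.95e-06), at 10.9 ± 0.423 FPKM in ra1, 3.81 in wild type and 0.799 in ra3. Against wild type, the ra1 call of GRMZM2G056022 was lost without wild-type replicate 2 (adjusted p 0.0646), and its ra3 call without wild-type replicate 1 or 3 (0.136 and 0.0595) and without ra3 replicate 1 or 3 (0.122 and 0.111); the losses of its ra2 call are given in the report. The calls of GRMZM2G070500 were lost without any 1 of the libraries compared, at adjusted p of 0.0628 to 0.2 in ra1 and 0.105 to 0.194 in ra3, and under the common median (0.317 and 0.182).

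The genes called between ra1 and wild type at 2 mm were enriched on chromosome 7, where ra1 is. They numbered 14 of 32 there, or 43.75%, against 8.06% of the genes tested (Fisher's exact test, two-sided, p 5.43e-08). Position along the chromosome was not tested. Of the 32, 18.75% were below 0.1 FPKM in all 12 B73 libraries (6 genes, against 25 of the 21657 tested, exact p 1.1e-12). Donor DNA that came along with the ra1 allele, and alleles silent in B73, may therefore account for part of the calls. A change that builds up as ears grow is argued against for the calls on chromosome 7, since their 1 mm log2 fold changes were at a median 0.924 of those at 2 mm and 14 of 14 had the same direction, with bd1 as an exception (lowest ratio 0.00413). On the other chromosomes that ratio was 0.502, with 17 of 18 in the same direction, which leaves a change that builds up open there, and an effect of ra1 itself on these genes stays open as well. Neither donor DNA nor the loss of ra1 is excluded for bd1, which lies on chromosome 7 at 172207717 while ra1 is at 110331505. On the same chromosome ra3 is at 166856424, nearer to bd1 than ra1 is.

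More genes were higher than lower from ear tip to base. A few genes taking most of the FPKM in the tip is argued against, since the 10 highest genes took only 0.874 percentage points more of it there (4.45% in tip, 3.58% in base libraries). Library scaling may account for the whole excess: among called genes that changed by at least 2 on the log2 scale the ratio of higher to lower genes was 3.71 as deposited (386 and 104) and 0.931 with the libraries at a common median (190 and 204). The shift sets the median difference of the libraries to about 0, and so moves this ratio toward 1 whatever raised it. The biological alternative, that more genes are truly higher in the base, stays open and untested, since FPKM carries no absolute scale.

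Tassel libraries with the same replicate number deviated together from their stage means, with correlations across genes of at least 0.178 in every pair of stages. A library batch shared by a number may produce this, though the labels name no batch. Unequal totals may produce it as well. Replicate 1 had the higher sum of FPKM at each stage (506208.9 against 375123.3, 521544.8 against 308581.2 and 494867.1 against 291579.5). The correlations were computed without the common median, so that cause was not tested. Pools of different age stay open: the difference between replicates correlated with the ear base to tip change at 0.156, 0.0915 and 0.187 in stages 1, 2 and 3, of 1 sign, but under the 0.3 set for that cause and not all under the 0.1 set against it. Batch and age of the pool cannot be told apart, since each number holds 1 library per stage.

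For the 6 comparisons of 3 against 3 libraries at 2 mm, the 10 splits of the 6 libraries are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real counts were 32, 5 and 7 for ra1, ra2 and ra3 against wild type, and 72, 108 and 69 for ra1 against ra2, ra1 against ra3 and ra2 against ra3, with 0, 0, 1, 0, 1 and 0 in the highest other split. Between mutants, where the numbers pair the libraries, 4 of the 10 splits part all pairs, the real one included, and the highest of the other 3 gave 0 genes.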

How the results depend on the processing

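The alternative chosen only after the data were seen is the replicate block with median shift. The counts called in ear middle against tip (13255) and base against tip (12413) stayed within 1.5 times under each alternative run, except base against tip without base replicate 1 (8233). For the values of named genes, 197 of 250 kept their direction and side of the threshold in a fit over the compared groups only, 185 of 255 under the median shift, 192 of 255 with no filter, 218 of 255 with a pseudocount of 0.1, 238 of 255 with the replicate block and 210 of 255 with the block and the shift; with 1 library left out 755 of 1083 did, and 44 more values were missing because the gene was not tested in the libraries that remained. Under the median shift, and under the block with it, ocl5 turned to -0.0916 in ear middle against tip and to -0.0524 in base against tip, and ra2 to -0.0730 in base against tip. For every change of count or direction below and above, the cause was not tested.

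With a pseudocount of 0.1, the counts were 74 in ear base against middle, 0 in tassel stage 3 against 2, 3 and 7 in 1 mm ra2 and ra3 and 17 in 2 mm ra1. With no filter they were 2 in ear base against middle, 0 in tassel stage 3 against 2 and against 1, 13, 15 and 22 in 1 mm ra1, ra2 and ra3, 52 and 8 in 2 mm ra1 and ra2, 25 in wild type 2 mm against 1 mm, and 1, 1 and 3 for the change of the ra1, ra2 and ra3 effect between sizes. Under the median shift they were 0 in tassel stage 3 against 2, 9 in stage 3 against 1, 3 and 0 in 1 mm ra1 and ra3, and 60, 18 and 12 in 2 mm ra1, ra2 and ra3. In a fit over the compared groups only they were 611 in ear base against middle, 2, 2 and 80 in tassel stage 2 against 1, 3 against 2 and 3 against 1, 1, 7 and 161 in 1 mm ra1, ra2 and ra3, 2, 0 and 1 in 2 mm ra1, ra2 and ra3, and 31, 25 and 22 in ra1 against ra2, ra1 against ra3 and ra2 against ra3. Of the 103 list calls at the preset correlation, 0 held with an estimated one. Of the 12 tests of the ear position genes in mutants, 10 were called, 5 with sets of genes that changed by at least 1 on the log2 scale and 0 with an estimated correlation.

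With the replicate number as a block, the counts were 101 in ear base against middle, 0 in tassel stage 3 against 2 (M14 at 0.0895), 72 in stage 3 against 1 (38 higher and 34 lower, without bx2, GRMZM2G127379 and GRMZM2G174562 at 0.0544 each), 4, 3 and 0 in 1 mm ra1, ra2 and ra3, 54 and 8 in 2 mm ra1 and ra2, 19 in wild type 2 mm against 1 mm, and 5 genes called the same way in at least 2 mutants. With the block and the median shift they were 2 in tassel stage 2 against 1, 0 in stage 3 against 2, 167 in stage 3 against 1, 14 and 12 in 1 mm ra1 and ra3, 133, 32 and 28 in 2 mm ra1, ra2 and ra3, 191 in ra1 against ra3 and 125 in ra2 against ra3. Between mutants, where the numbers pair the libraries, the block changed the calls given in the report and no other call of a list or of a gene the report names. Elsewhere a correlation was under 0.1 or only 2 numbers were shared, so the numbers were not taken to pair the libraries: the deviations of same-numbered libraries correlated at -0.196 to 0.0683 in ear sections, 0.178 to 0.653 in tassels, -0.00565 to 0.398 in 1 mm ears, and between wild type and mutants at 2 mm at -0.246 to 0.552.

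Leaving out 1 library, which leaves a lone sample in groups of 2 that is assumed to vary like the other groups, gave lowest and highest counts of 9432 and 13826 in ear middle against tip, 8233 and 13076 in base against tip, and 0 and 28 in base against middle. They were 1 and 18 in tassel stage 2 against 1, 0 and 28 in 3 against 2 and 16 and 94 in 3 against 1. At 1 mm they were 0 and 0 for ra1, 0 and 1 for ra2 and 0 and 20 for ra3, and at 2 mm 5 and 21 for ra1, 3 and 5 for ra2 and 0 and 7 for ra3. They were 0 and 11 in wild type 2 mm against 1 mm, 41 and 81 in ra1 against ra2, 68 and 85 in ra1 against ra3 and 23 and 44 in ra2 against ra3. For the change of effect between sizes they were 0 and 0 for ra1, 0 and 1 for ra2 and 0 and 2 for ra3. The correlation of ear and tassel changes ran from 0.0350 to 0.315. Depth, inferred at 3366725 to 23607624 fragments per library, limits how low a level can be read; the tables hold no counts, so its effect on the calls was not tested.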

Other observations

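Several gene groups outside the fixed lists moved relative to all genes along the ear and in the tassel, by camera at the preset correlation alone. Of 10 core histone genes 9 rose in ear base against tip (9 over the list alone; 6 under the common median) and none fell, at 0.52 relative to all genes (camera adjusted p 0.0287; 0.946 with an estimated correlation). Of 37 ribosomal protein genes 7 rose and 14 fell, at -0.66 (2.10e-05; 0.933), with 3 and 19 under the common median. Of 6 benzoxazinoid genes, a defence pathway of grasses, 1 rose and 5 fell in ear base against tip, at -1.33 (8.74e-05; 0.662), and under the common median 5 fell and none rose. In tassels 1 of 7 benzoxazinoid genes passed from stage 1 to stage 3, bx2, which did not pass under the common median (adjusted p 0.159) or without stage 1 replicate 1 (0.0544), and 6 rose adjusted over the list alone (4 under the common median), at 1.44 (5.91e-09; 0.773); the difference from the ear was not tested. Tassel ribosomal protein genes stood at -0.85 (9.52e-10; 0.880).

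On chromosome 7 lay 22 of the 72 genes called in ra1 against ra2 (30.56%; Fisher's exact p 2.64e-08) and 29 of the 108 in ra1 against ra3 (26.85%; 4.67e-09). In ra2 against ra3, 4 of 69 lay on chromosome 7 (5.80%; 0.658), which holds ra3, and 14 of 69 on chromosome 3 (20.29%; 0.0171, adjusted 0.0308), which holds ra2. The authors' tables with 1 value per group differ from the per-library values. Their median log2 ratio of ear base over tip is 0.257, against 0.467 here (r 0.842 across genes). For ra1 over wild type at 2 mm it is 0.625, against 0.341 (r 0.366 across genes). At 2 mm the r across genes was 0.469 for ra2 and 0.640 for ra3 over wild type. Fold changes of single genes thus differ as well as the medians, and the cause was not tested.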
